A study of Sus scrofa with 9 samples.

How the data were processed

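The series measured microRNAs (miRNAs) in spleen of the Ningxiang pig, an indigenous Chinese breed, at postnatal days 30, 90 and 210, with 3 libraries per age. Per the labels, total RNA was extracted with Trizol, small RNA libraries were made with a TruSeq Small RNA kit, and the raw reads passed through the program ACGT101-miR, which removed adapter dimers, junk, low-complexity reads, common RNA families (rRNA, tRNA, snRNA and snoRNA) and repeats. The aligner, the genome build, the miRNA database and the scaling method are not given in the sources used here. Because the genome build is not given, no positions are printed.

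The deposited table holds, per the file headers, normalised read numbers per mature sequence, a signal scaled per library by the authors and not a raw count. It lists 980 entries in 9 library columns. 5 entries that repeated the values and the name or mature sequence of another were dropped, which left 975, of which 453 carry the name of a pig miRNA and 522 are candidates predicted by the authors (names that begin with PC). Names are written here without the species prefix and without any suffix after a _ sign, except for candidates and where the suffix tells a pair of entries apart. Names that end in p5 or p3 are written as in the table.

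The depth behind the values was read from the table itself. Between 88.1% and 92.7% of the non-zero values of a library were whole multiples of a step that differed between libraries (tolerance 0.01 of a step), and the commonest low value was taken to be 5 reads. On that assumption the libraries held between 4.54 and 9.34 M reads (M, mega), and between 97.6% and 99.5% of the non-zero values stood for at least 5 reads, so most sequences with fewer reads are listed at 0. The value that stands for 5 reads ran from 3.62 to 8.001, so the level below which most sequences are listed at 0 was highest in day 210 replicate 3. No raw counts are held, so no counting intervals are given, and low values rest on few reads. PCR copies were not removed by molecular identifiers as far as the labels tell.

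Because the values are normalised, limma 3.58.1 in R 4.3.3 was used, as fixed before the data were examined for that case. The model was fitted to log2(value + 1) with a mean per age over all 9 libraries, and empirical Bayes moderation with a mean-variance trend. Sequences with a value of at least 5 in at least 3 libraries were tested, which kept 630 (406 named as pig miRNAs and 224 candidates); the others held 0.00736% of all values. The 3 pairwise comparisons and an F test over the 3 ages used Benjamini-Hochberg adjusted p with a threshold of 0.05. Group values are means ± SD over 3 libraries, and log2 fold changes are given ± SE. Fold changes are ratios of geometric means of value + 1. Where a sequence is listed at 0 in every library of an age, no fold change is given.

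Lists of miRNAs were fixed before the data were examined, from textbook knowledge of families, genomic clusters and cell types, and matched by name and arm: lymphoid, hematopoietic miR-142, myeloid, erythroid, endothelial, smooth muscle and fibroblast, striated muscle, epithelial, pancreas and liver, and neural miRNAs, the let-7, miR-15/16, miR-29, miR-30 and miR-34/449 families, the miR-17-92 cluster with its paralogs, the DLK1-DIO3 cluster, the miR-424/503/450/542 cluster, and the IGF2/H19 locus. Of the 19 lists 18 matched the table, and 14 with at least 3 tested members went through limma's competitive list test (camera) with a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison. miR-363 and let-7e each stand in a pair of lists. Calls of members are also given adjusted over the list alone.

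The miRNAs named in the text follow a rule fixed before the data were examined. They are the 10 largest rises and 10 largest falls per comparison among sequences with an adjusted p under 0.05, a mean of at least 10 in 1 of the compared ages and no overlap between the libraries of both ages, then the members of the lists with the smallest p or the highest level, then the 10 most abundant miRNAs. The share of all values held by the 10 most abundant miRNAs was compared by exact two-sided permutation tests, which cannot go below p = 0.1 with 3 libraries against 3.

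The procedure was tested on simulated data shaped like the comparison of day 210 with day 30. It recovered 19 of 50 sequences changed by a log2 of 1 (38.0%) and 29 of 50 changed by a log2 of 2 (58.0%), with 3 false calls among 530 unchanged sequences and 0 calls where nothing was changed. It found the shifted list (adjusted p 4.19e-11) and none of 20 random lists. The simulated noise was independent between sequences, so lists whose members vary together were not tested. Each sequence also had the same simulated spread at every age. The 3 false calls therefore do not speak to data in which the libraries of 1 age spread more widely. In the real data the estimated inter-gene correlation was 0.881 for the miR-29 family and 0.622 for the DLK1-DIO3 cluster.

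Alternatives fixed before the data were examined were a pair of rescalings (median ratio and TMM factors), no filter and a stricter filter (at least 50), pseudocounts of 0.5 and 5, a block for the replicate number, no mean-variance trend, sample weights, a fit of only the ages compared, an estimated inter-gene correlation, 5 or 20 instead of 10 abundant miRNAs, and leaving out each library in turn. A common reporting floor, a correction for a per-library loess trend on GC content, only pig miRNAs, and only sequences with a GC content of at most 60% were added after seeing the data. Neighbouring miRNA genes were taken from a gene table of the pig assembly Sscrofa11.1, which served for names and neighbours only.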

Results

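Spleen miRNAs were profiled at postnatal days 30, 90 and 210 in Ningxiang pigs, with 3 libraries per age. The estimated depth was 7.33, 6.97 and 9.02 M reads in the day 30 libraries, 6.75, 6.64 and 9.34 M at day 90, and 7.08, 6.16 and 4.54 M at day 210 (replicates 1, 2 and 3). The number of sequences above 0 was 657 ± 25.5 at day 30, 641 ± 36.5 at day 90 and 576 ± 35.6 at day 210 (mean ± SD, n = 3). The normalised values of a library summed to 6.47 ± 0.220 M at day 30, 6.77 ± 0.318 M at day 90 and 7.59 ± 0.346 M at day 210. No fit set these sums equal, so small rises of abundant miRNAs at day 210 were not tested as rises in share. The authors' candidates held between 0.499% and 0.773% of all values, with the highest share in day 210 replicate 3. Nothing in the labels says that the libraries of an age came from separate animals, so the p-values measure only the spread between these libraries.

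The spleen libraries were dominated by a few miRNAs. miR-26a was the most abundant with a mean value of 975237 over the 9 libraries, 14.2% of all values. It was followed by miR-143-3p, a miRNA of smooth muscle (12.2%), miR-191 (7.68%), miR-99a-5p (4.10%), miR-145-5p, transcribed together with miR-143 (4.06%), miR-125b (3.27%), miR-30d (2.73%), miR-27b-3p (2.72%), miR-339 (2.67%) and miR-30c-5p (1.90%). The order is that of the mean over the 9 libraries; among these 10 the first 3 and the last kept their places at every age, and the order of the other 6 differed between ages. The 10 most abundant miRNAs of each library, chosen library by library, held 54.6 ± 0.371% of the values at day 30. Their share was 54.0 ± 1.38% at day 90 and 58.5 ± 1.28% at day 210. The difference of -0.645 percentage points between day 90 and day 30 was within the spread between libraries (exact permutation p = 0.5). The share was 3.88 points higher at day 210 than at day 30 and 4.53 points higher than at day 90 (exact permutation p = 0.1 for each, the smallest that 3 against 3 allows), and all 3 day 210 libraries lay above every other library.

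Libraries of day 210 stood apart from those of the earlier ages and from each other. Spearman correlations across sequences ran from 0.954 to 0.974 within day 30, from 0.967 to 0.972 within day 90 and from 0.931 to 0.956 within day 210, against 0.882 to 0.962 between ages; sequences are not independent replicates. On the first principal component the day 210 libraries lay at 8.99, 28.0 and 33.3 (replicates 1, 2 and 3), and the other 6 between -15.2 and -7.85. In the same order their estimated depth fell (7.08, 6.16 and 4.54 M reads) and their entries at 0 rose (362, 403 and 433). The depth of day 210 replicate 1 lay within the range of the earlier ages. Depth and age were not separated on this component. On the second, day 210 replicate 3 lay at 19.8 and the other day 210 libraries at -13.3 and -14.6.

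**Figure D1:**
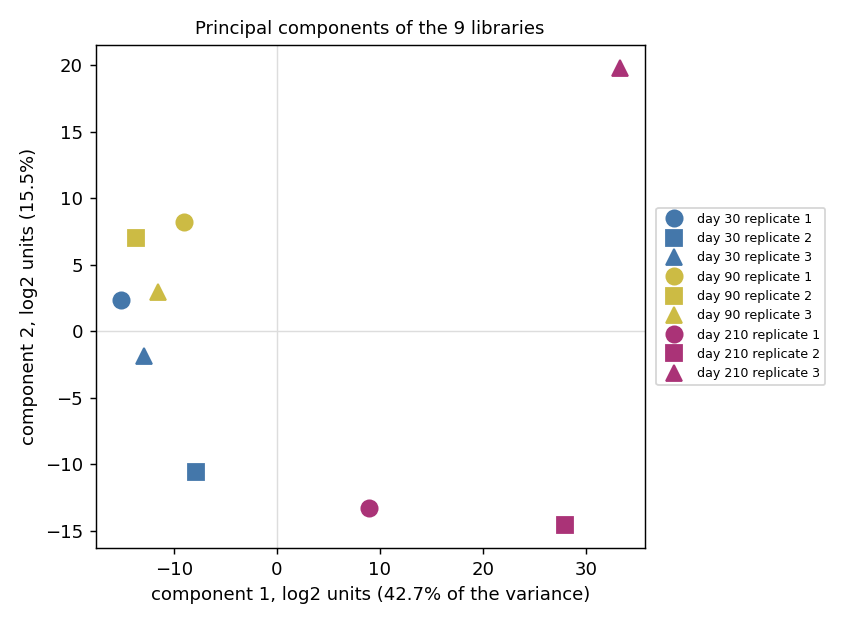
Each point is 1 library on the first (horizontal, 42.7% of the variance) and second (vertical, 15.5%) principal component of log2(value + 1) over the 630 tested sequences, in log2 units; colour gives the age and shape the replicate. The day 210 libraries lie between 8.99 and 33.3 on the first component, to the right of all others, and day 210 replicate 3 is apart on the second at 19.8.

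The first comparison asks which spleen miRNAs differed between day 30 and day 90. miR-29a-3p, of a family known for targeting collagens and other matrix transcripts, rose 2.12-fold, from 35122 ± 3272 to 74106 ± 1849.7 (mean ± SD, n = 3; log2 1.08 ± 0.11, adjusted p 0.00175 by limma); its sequence in the table is TAGCACCATCTGAAATCGGTT. miR-150, a miRNA of mature B and T cells, rose 1.68-fold, from 47705 ± 4012 to 80084 ± 8547 (log2 0.75 ± 0.12, adjusted p 0.0190). miR-184 rose from 49.1 ± 24.9 to 303 ± 68.5 (log2 2.72 ± 0.40, adjusted p 0.0122). miR-323, from the imprinted DLK1-DIO3 cluster, fell by 1.39 ± 0.26 on the log2 scale, from 456 ± 115 to 172 ± 32.9 (adjusted p 0.0330; 0.0659 after the GC correction). mir-325-p3 fell by 2.89 ± 0.56, from 70.9 ± 1.09 to 10.01 ± 7.18 (adjusted p 0.0427). miR-452 and mir-452-p3, both from 1 precursor, were listed at 0 in all day 30 libraries. At day 90 miR-452 stood at 20.1, 19.3 and 13.7 (adjusted p 0.0106) and mir-452-p3 at 14.4, 16.3 and 19.004 (adjusted p 0.0286).

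These 7 miRNAs, 5 higher and 2 lower at day 90, were all that passed the threshold among 630 tested by limma, while 96 had an unadjusted p under 0.05; the median log2 fold change of all was -0.04. With sample weights 40 were higher and 41 lower, and a fit of only the ages compared also called more than 7. miR-29a-3p alone kept its call under all 23 alternatives, and the adjusted p of the others reached 0.265 at most when 1 library was left out. The count was 3, 4 and 2 without day 30 replicates 1, 2 and 3, and 1 without day 90 replicate 1 or 2. It was 12 and 20 without day 210 replicates 2 and 3. Here the day 210 libraries enter only through the estimated spread and the filter, which kept 621 sequences without day 210 replicate 3.

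By list, 3 of the 14 tested lists were called higher and 3 lower at day 90, and 0 of the 6 calls held with an estimated correlation. All 3 members of the miR-29 family had higher values (median log2 fold change 1.08, list adjusted p 3.83e-04). miR-29a passed the threshold over all miRNAs and 3 passed adjusted over the list alone, with miR-29b at 1.08 ± 0.41 and miR-29c at 0.90 ± 0.32; the list had adjusted p = 0.372 with an estimated correlation (range over its 21 alternatives 6.14e-05 to 0.372). Of the 12 lymphoid miRNAs 8 had higher values (median 0.21, adjusted p 0.00997), with 1 called and 4 adjusted over the list alone. Its highest were miR-146b (log2 1.24 ± 0.35, adjusted p 0.156), miR-155-5p (log2 0.92 ± 0.22, adjusted p 0.107) and miR-146a-5p (log2 0.81 ± 0.22, adjusted p 0.156), all known as miRNAs induced in activated immune cells. The lymphoid list had adjusted p = 0.372 with an estimated correlation (range over its 21 alternatives 0.00354 to 0.372). All 5 members of the miR-15/16 family, known for restraining the cell cycle, had higher values (median 0.34, adjusted p 0.0320; 0 called by limma and 0 adjusted over the list alone), with miR-195 at 0.57 ± 0.23. That list had adjusted p = 0.374 with an estimated correlation (range over its 21 alternatives 0.0101 to 0.374), and its adjusted p was 0.119 without day 30 replicate 2, 0.0602 without day 30 replicate 3 and 0.0606 without day 90 replicate 3. It also missed the threshold with the stricter filter (0.0668), the GC correction (0.0777), pig miRNAs only (0.0741) and a GC content of at most 60% (0.0513).

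Of the 22 tested members of the DLK1-DIO3 cluster, a large imprinted miRNA cluster, 20 had lower values at day 90 (median -0.90, adjusted p 4.93e-05). Besides miR-323, the only member called over all miRNAs, 1 more passed adjusted over the list alone (2 in all); miR-370 stood at -1.26 ± 0.31, miR-432-5p at -1.58 ± 0.52 and miR-127, the most abundant, at -0.67 ± 0.23. The list had adjusted p = 0.427 with an estimated correlation (range over its 21 alternatives 5.80e-10 to 0.427). In the X-linked cluster of miR-424, miR-503, miR-450 and miR-542, 7 of 8 members had lower values (median -0.87, adjusted p 0.00155), with 0 called by limma over all miRNAs and 4 adjusted over the list alone. Examples were miR-424-3p (log2 -1.32 ± 0.30, adjusted p 0.0857), miR-450b-5p (-1.26 ± 0.37) and miR-450c-5p (-0.78 ± 0.23), while miR-542-5p, named after its values were seen, stood at 1.87 ± 0.83, but at 0.01 with the common floor, since all its values lay near the level of 5 reads. This X-linked cluster had adjusted p = 0.374 with an estimated correlation (range over its 21 alternatives 2.96e-05 to 0.374). Of 13 smooth muscle and fibroblast miRNAs 10 had lower values (median -0.29, adjusted p 0.0491; 0 called by limma and 0 adjusted over the list alone), among them miR-143-5p at -0.57 ± 0.16 and miR-214-3p at -0.50 ± 0.17. The call had adjusted p = 0.525 with an estimated correlation (range over its 21 alternatives 4.45e-04 to 0.525), and it ended in 7 of the 9 fits that left out 1 library, all but those without day 30 replicate 1 and day 90 replicate 3 (highest adjusted p 0.367, without day 90 replicate 1). It also ended with a pseudocount of 5 (0.0519), the common floor (0.0711), the GC correction (0.0693) and pig miRNAs only (0.0715).

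**Figure D2:**
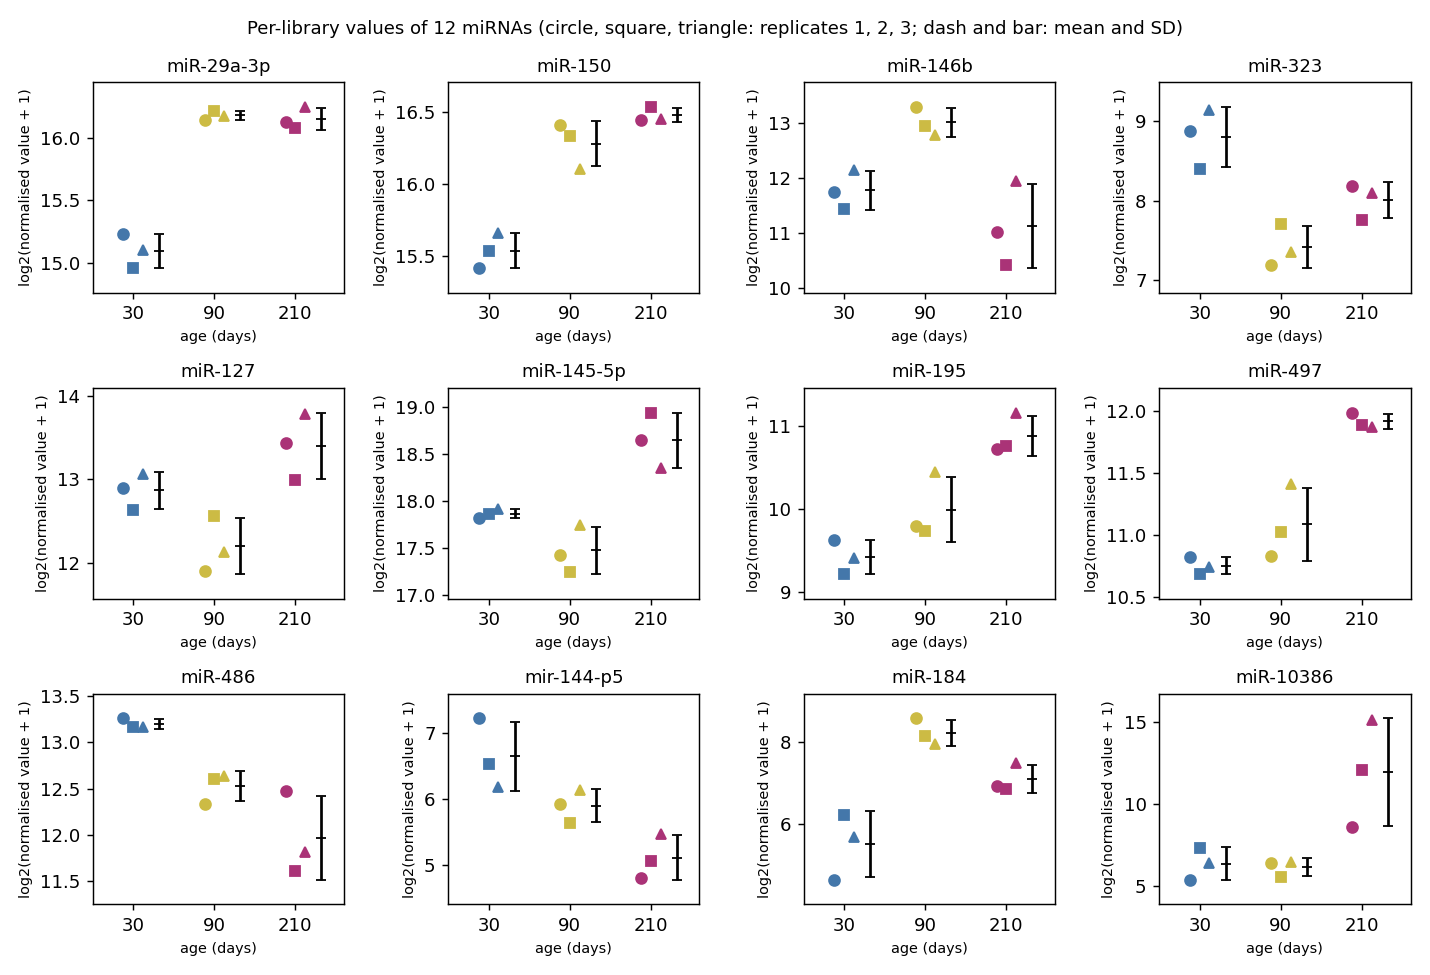
Each panel shows 1 miRNA, with age in days on the horizontal axis and log2(normalised value + 1) on the vertical axis, which differs between panels and does not start at 0; points are libraries, and the dash and bar give mean and SD of 3. miR-29a-3p and miR-150 are higher in every day 90 and day 210 library than in any day 30 library, and miR-10386 spreads from 391 to 35846 at day 210 before the logarithm.

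The second comparison sets the oldest against the youngest spleens, day 210 against day 30. miR-29a-3p was 2.08-fold higher at day 210 (72769 ± 4444; log2 1.05 ± 0.11, adjusted p 0.00220), and miR-150 1.92-fold higher (91499 ± 3275; log2 0.94 ± 0.12, adjusted p 0.00388). miR-195 and miR-497, which share a primary transcript and the seed of the miR-15/16 family, rose 2.77-fold from 688 ± 98.6 to 1910.5 ± 335 (adjusted p 0.00577) and 2.24-fold from 1722 ± 82.5 to 3867 ± 169 (adjusted p 0.00388). The smooth muscle miRNA miR-145-5p rose 1.72-fold, from 238775 ± 7674 to 415787 ± 84456 (adjusted p 0.0232), and the erythroid miRNA miR-486 fell by 1.23 ± 0.21 on the log2 scale, from 9392 ± 352 to 4134 ± 1372 (adjusted p 0.00873; 0.0538 without day 30 replicate 1).

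In all 58 of 630 sequences passed the threshold, 29 higher and 29 lower at day 210, and 185 had an unadjusted p under 0.05; the median log2 fold change was -0.15. The called comprised 43 pig miRNAs (22 higher, 21 lower) and 15 candidates (7 higher, 8 lower). Of 31 named and called, 5 kept their call under every alternative that tested them: miR-29a-3p, miR-150, miR-195, miR-497 and miR-371-5p. The first 4 were tested in 23 alternatives and miR-371-5p in 19. It passed the filter only through the day 210 libraries, so each fit without a day 210 library left it untested, as did the stricter filter. The adjusted p of the other named sequences reached 0.149 at most when 1 library was left out. Of these 31 calls the common floor ended 15, the fit without the mean-variance trend 14 and the fit of only the ages compared 21. The split also moved, to 15 higher and 25 lower without the mean-variance trend, 83 and 34 with the GC correction, and 7 and 19 without day 210 replicate 2. The count was 9 without day 30 replicate 1, 21 without day 30 replicate 3, 26 without day 210 replicate 2 and 90 without day 210 replicate 3.

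Among the 10 largest rises by log2 fold change were 7 sequences with a GC content of at least 70%, and the day 210 values spread widely. miR-371-5p, whose family is known from pluripotent and germ cells, was listed at 0 at days 30 and 90 and stood at 32.0001, 634 and 182 at day 210 (adjusted p 0.00388). mir-10386-p3 stood at 0, 16.2 and 0 at day 30 and 45.9, 874 and 6516 at day 210 (replicates 1, 2 and 3; log2 7.96 ± 1.74, adjusted p 0.0229). miR-10386 from the same precursor went from 40.7, 163 and 83.98 to 391, 4396 and 35846 (log2 5.57 ± 1.29, adjusted p 0.0266), and mir-4332-p5 from 10.2, 92.5 and 28.2 to 149, 387 and 1246 (log2 3.74 ± 0.98, adjusted p 0.0438). Of the 10 largest rises 6 were candidates. PC-5p-2838_1485 and PC-5p-24063_140 were listed at 0 at day 30 and stood at 17.1, 275 and 2680.2 and at 7.47, 27.1 and 179 at day 210 (adjusted p 0.0152 and 0.0201). The other 4 rose by 6.41 ± 1.59 (PC-3p-5107_766), 5.81 ± 1.32 (PC-5p-1854_2553), 4.47 ± 0.95 (PC-3p-42837_55) and 4.36 ± 0.93 (PC-5p-29308_106) on the log2 scale. Among the 29 risers 8 had a GC content of at least 70%, against 56 of the 630 tested; with the GC correction 8 of 83 risers did. The summed values of those 8 were 1834, 5118 and 21936 in day 210 replicates 1, 2 and 3, against at most 1215 in a day 30 library, and most of the sum in replicate 1 (1428) and in that day 30 library (1041) came from mir-4332-p3. With the same 630 sequences tested, 6 of the 8 passed without day 210 replicate 3. Of these 6, 3 reached the filter value of 5 in all 3 day 210 libraries and in no other. The loss of any 1 of those libraries takes them below the filter. With the filter applied again without replicate 3, 3 passed. With the common floor the rises of mir-10386-p3, miR-10386 and mir-4332-p5 were 5.85, 5.57 and 3.74 and their calls ended (adjusted p 0.0662, 0.0662 and 0.0810). It also ended the calls of PC-3p-5107_766 (5.10, adjusted p 0.0621), PC-5p-1854_2553 (5.55, 0.0662), PC-5p-29308_106 (2.72, 0.0569), PC-5p-2838_1485 and PC-5p-24063_140, while PC-3p-42837_55 (2.94) and miR-371-5p stayed called.

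The largest falls were in scarce sequences. miR-10390 went from 107, 151 and 159 to 24.5, 0 and 0 (adjusted p 0.0152) and its shorter form miR-10390_L-5 from 18.7, 20.03 and 15.2 to 0 in all day 210 libraries (adjusted p 0.0377). Also listed at 0 throughout day 210 were miR-33b-3p, from an intron of the sterol regulator gene SREBF1 (21.2, 13.4 and 23.9 at day 30; adjusted p 0.00388), mir-218b-p3 (28.9, 4.77 and 24.6; adjusted p 0.0152) and mir-20b-2-p3 (19.5, 13.4 and 3.62; adjusted p 0.0229). miR-4331-5p fell by 4.24 ± 1.10 on the log2 scale (adjusted p 0.0412). The candidates PC-5p-34450_83, PC-3p-36331_75, PC-3p-33614_86 and PC-5p-16308_225 had log2 changes between -4.58 ± 0.70 and -3.72 ± 0.71. With the common floor miR-10390 (-3.43), miR-4331-5p (-2.13) and these candidates (-2.30, -1.65, -1.65 and -2.17) stayed called with smaller changes, and the calls of the 4 named sequences at 0 throughout day 210 ended. Of the 29 falls 16 had a mean under 50 over the 9 libraries, and the estimated depth was 5.93 ± 1.29 M reads at day 210 against 7.77 ± 1.10 M at day 30.

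By list, only the miR-29 family passed between day 210 and day 30: all 3 members had higher values (median 1.05, adjusted p 0.0139; 1 called, 3 adjusted over the list alone), with miR-29b at 1.21 ± 0.41 and miR-29c at 0.75 ± 0.32. It had adjusted p = 0.672 with an estimated correlation (range over its 21 alternatives 0.00209 to 0.672), and 0.0721 without day 30 replicate 2. Of the 4 erythroid miRNAs miR-486 and mir-144-p5 fell, the latter from 104 ± 39.4 to 34.05 ± 8.41 (adjusted p 0.0266), and 3 passed adjusted over the list alone with miR-144 (log2 -1.23 ± 0.35, adjusted p 0.0542). miR-451, the most abundant red cell miRNA in this list, stood at 13737, 6113 and 8809 at day 30 and 7529.6, 5005 and 20851 at day 210 (log2 0.03 ± 0.49, adjusted p 0.978), and the direction of its difference turned in some of the alternatives, to -0.01 with TMM rescaling, -0.25 without day 30 replicate 2 and -0.56 without day 210 replicate 3. The erythroid list as a whole had a median of -1.23 and missed the threshold (adjusted p 0.0896). In the smooth muscle and fibroblast list miR-145-5p rose, as did miR-99a-5p (0.58 ± 0.13, adjusted p 0.0257). The same 2 of 13 passed adjusted over the list alone, while miR-143-3p stood at 0.31 ± 0.15. The list test gave an adjusted p of 0.173. Among the striated muscle miRNAs miR-133b rose (log2 1.62 ± 0.36, adjusted p 0.0255) and among the epithelial miRNAs miR-205 rose (log2 2.59 ± 0.63, adjusted p 0.0324), and these lists had adjusted p of 0.109 and 0.405. In the let-7 family let-7c, encoded beside miR-99a, rose (log2 0.51 ± 0.11, adjusted p 0.0209), with 1 of 8 higher and 2 lower adjusted over the list alone and a list adjusted p of 0.959. The lymphoid list gave 0.219 (1 of 12 called, 2 adjusted over the list alone), with miR-181c at 0.51 ± 0.14.

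The third comparison asks what differed between day 90 and day 210. miR-145-5p rose 2.26-fold, from 183735 ± 32934 to 415787 ± 84456 (log2 1.17 ± 0.17, adjusted p 0.00683). miR-127 of the DLK1-DIO3 cluster rose from 4780.1 ± 1137 to 11097 ± 2971 (log2 1.21 ± 0.23, adjusted p 0.0185). miR-146b, known as a brake on inflammatory signalling, fell by 1.89 ± 0.35 on the log2 scale, from 8357 ± 1563 to 2453 ± 1322 (adjusted p 0.0149). miR-133a-3p, a muscle miRNA, rose by 1.04 ± 0.20 (adjusted p 0.0185). miR-224 was listed at 0 in all day 210 libraries after 32.6, 50.8 and 33.4 at day 90 (adjusted p 0.00190), and mir-452-p3, from a neighbouring precursor, after 14.4, 16.3 and 19.004 (adjusted p 0.0136).

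In all 51 of 630 sequences passed, 26 higher and 25 lower at day 210 (34 pig miRNAs and 17 candidates), and 171 had an unadjusted p under 0.05; the median log2 fold change was -0.14. miR-145-5p, miR-224 and PC-5p-34450_83 kept their call under every alternative that tested them, of 28 named and called, and the adjusted p of the others reached 0.161 at most when 1 library was left out. Of these 28 calls the common floor ended 16, the fit without the mean-variance trend 15 and the fit of only the ages compared 16. The split was 7 higher and 17 lower without the mean-variance trend, 51 and 22 with the GC correction, and 3 and 10 without day 210 replicate 2. The count was 8, 10 and 22 without day 90 replicates 1, 2 and 3, 13 without day 210 replicate 2 and 112 without day 210 replicate 3. The largest rises included mir-10386-p3 (8.41 ± 1.74), miR-10386 (5.77 ± 1.29) and mir-4332-p5 (4.27 ± 0.98), miR-371-5p from 0, and the candidates PC-3p-5107_766 (7.40 ± 1.59), PC-5p-2838_1485 (7.05 ± 1.53), PC-5p-1854_2553 (6.04 ± 1.32) and PC-3p-42837_55 (5.36 ± 0.95). PC-5p-29308_106 was listed at 0 at day 90 and stood at 25.6, 38.7 and 197 at day 210 (adjusted p 0.00796), and PC-5p-24063_140 was listed at 0 at day 90 as at day 30 (adjusted p 0.0205). Listed at 0 throughout day 210 were miR-33b-3p (32.6, 71.2 and 17.5 at day 90), mir-20b-2-p3 (21.1, 10.2 and 41.05), miR-219a (9.59, 21.3 and 15.96) and PC-5p-42886_55 (12.5, 12.2 and 15.96). miR-10390 (-4.21 ± 1.07), miR-7136-5p (-3.88 ± 0.94), PC-3p-36331_75 (-4.36 ± 0.93) and PC-5p-34450_83 (-5.31 ± 0.70) were also among the 10 largest falls. With the common floor these 4 stood at -2.10, -1.77, -2.25 and -3.02, and the calls of miR-10390 and miR-7136-5p ended (adjusted p 0.0502 and 0.0771). Among the rises mir-10386-p3 went to 6.16, PC-3p-5107_766 to 5.28, PC-5p-2838_1485 to 4.72 and PC-3p-42837_55 to 2.94, and of these only the last stayed called. The calls of miR-10386, mir-4332-p5, miR-371-5p, PC-5p-1854_2553, PC-5p-29308_106 and PC-5p-24063_140 also ended, as did those of miR-33b-3p, mir-20b-2-p3, miR-219a and PC-5p-42886_55.

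Of the 13 smooth muscle and fibroblast miRNAs 10 had higher values at day 210 than at day 90 (median 0.41, adjusted p 0.00253), with miR-145-5p called and 5 adjusted over the list alone. Further members were miR-125b (log2 0.94 ± 0.32, adjusted p 0.107), miR-143-3p (log2 0.47 ± 0.15, adjusted p 0.0924) and miR-99a-5p (log2 0.42 ± 0.13, adjusted p 0.0798). The list had adjusted p = 0.663 with an estimated correlation (range over its 21 alternatives 3.71e-05 to 0.663), and 0.0583 without day 90 replicate 1. The striated muscle list had a median of 0.78 and missed the threshold (adjusted p 0.0713), with 4 of 5 values higher. Adjusted over that list alone miR-133a-3p, miR-1 (0.78 ± 0.23) and miR-133b (from 162 ± 84.1 to 353 ± 98.9) were higher and miR-499-5p (-0.78 ± 0.28) lower. In the DLK1-DIO3 cluster 20 of 22 had higher values (median 0.81, adjusted p 1.11e-04; miR-127 called, 1 adjusted over the list alone), with miR-411 at 0.88 ± 0.29. It had adjusted p = 0.663 with an estimated correlation (range over its 21 alternatives 7.07e-10 to 0.663), and 0.0518 without day 210 replicate 3. This comparison and that of day 90 with day 30 use the same day 90 libraries, so their opposite medians are not independent; between day 210 and day 30 the cluster's median was 0.02 (mean -0.08, adjusted p 0.631). Of 10 members of the miR-17-92 cluster and its paralogs, known for promoting lymphocyte proliferation, 9 had lower values at day 210 (median -0.55, adjusted p 0.0348; 0 called by limma and 0 adjusted over the list alone), with miR-20a-5p at -0.75 ± 0.27 and miR-17-5p at -0.56 ± 0.21. It had adjusted p = 0.663 with an estimated correlation (range over its 21 alternatives 0.00122 to 0.663), and 0.0583, 0.195 and 0.163 without day 90 replicate 1, day 210 replicate 1 and day 210 replicate 2. The call also ended with the GC correction (0.223), the common floor (0.0581) and pig miRNAs only (0.0580). Lymphoid members parted: miR-342 rose (log2 0.56 ± 0.12, adjusted p 0.0205), miR-146b fell, and miR-146a-5p stood at -0.64 ± 0.22 (list adjusted p 0.735; 1 higher and 1 lower adjusted over the list alone). In the miR-15/16 family miR-195 (log2 0.89 ± 0.23, adjusted p 0.0395) and miR-497 (log2 0.83 ± 0.16, adjusted p 0.0185) rose, 2 of 5 adjusted over the list alone. The call of miR-195 ended in 11 of 23 alternatives and that of miR-497 in 5 of 23. The list's median of -0.20 differed in sign from its mean of 0.13 and its test (upward, adjusted p 0.684). In the neural list miR-128 fell (log2 -0.59 ± 0.14, adjusted p 0.0295; list adjusted p 0.953), but with the GC correction its change was -0.35 with an adjusted p of 0.139, and the call ended in 7 of 23 alternatives.

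**Figure D3:**
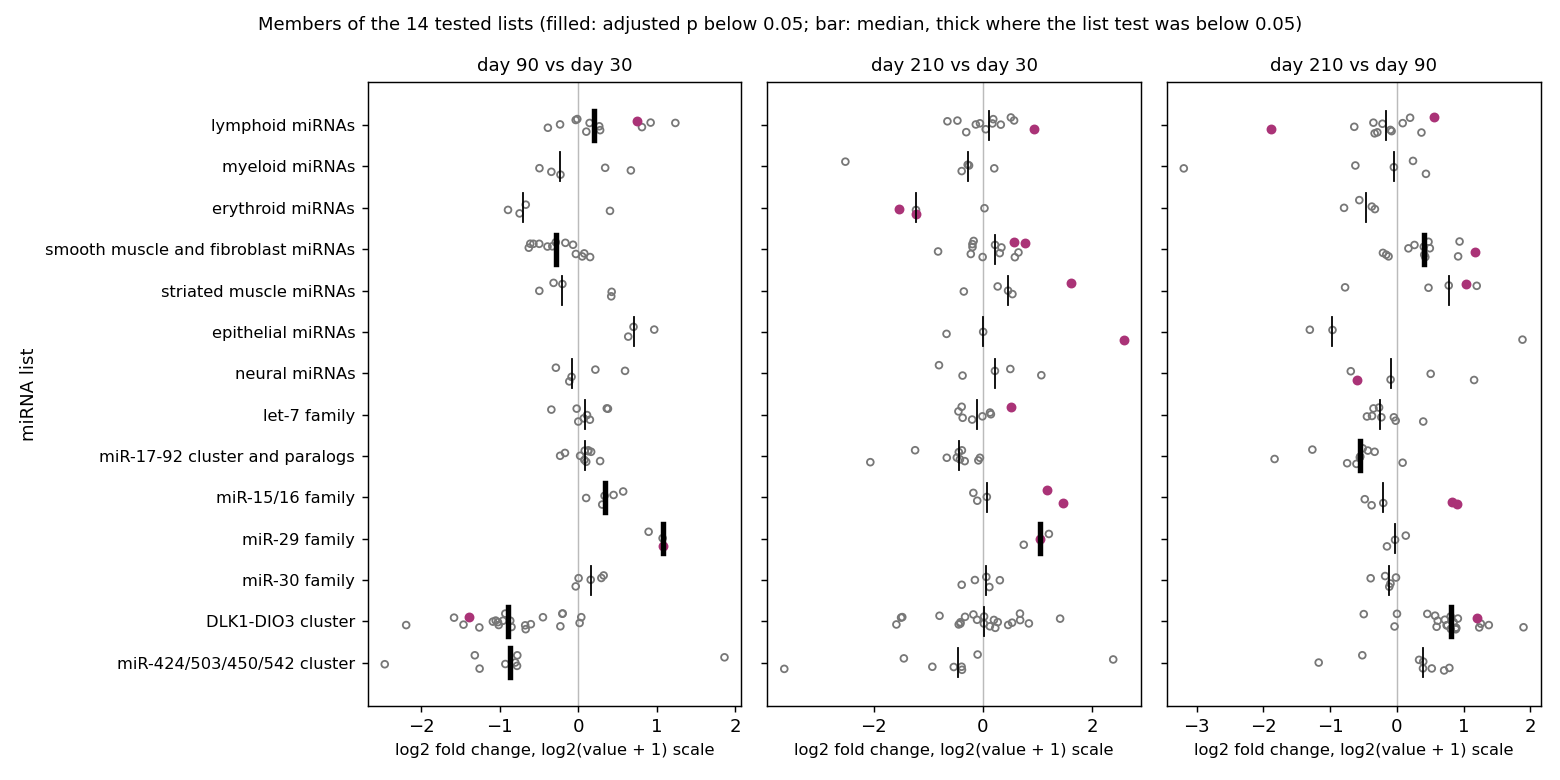
Each point is 1 member of a tested list, with the log2 fold change on the horizontal axis, the list on the vertical axis and 1 panel per comparison; filled points passed the threshold over all miRNAs, and the bar gives the list's median, thick where the list test passed. Most of the DLK1-DIO3 points lie below 0 in the first panel (median -0.90) and above 0 in the third (0.81), and both panels use the same day 90 libraries.

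The remaining list tests gave no call. The adjusted p in day 90 against day 30, day 210 against day 30 and day 210 against day 90 was 0.554, 0.405 and 0.823 for the myeloid miRNAs, and 0.321, 0.909 and 0.684 for the miR-30 family. Values for the erythroid list were 0.0734 between day 90 and day 30 (miR-486 -0.67 ± 0.21, miR-451 0.41 ± 0.49) and 0.320 between day 210 and day 90. The X-linked miR-424 cluster gave 0.230 between day 210 and day 30 and 0.317 between day 210 and day 90. Median and mean differed in sign for the neural list between day 90 and day 30 (-0.09 and 0.07) and between day 210 and day 90 (-0.09 and 0.06), and for the miR-30 family between day 210 and day 30 (0.06 and -0.01). Between day 210 and day 90 the epithelial list (median -0.96) and the miR-29 family (median -0.03) had a negative median and an upward test, with adjusted p of 0.953 and 0.953. Lists of 2 members were not tested. In the order of the comparisons above, miR-142-5p of blood cells stood at 0.71 ± 0.28, 0.14 ± 0.28 and -0.58 ± 0.28, and miR-142-3p at 0.43 ± 0.33, -0.19 ± 0.33 and -0.62 ± 0.33. The endothelial miR-126-3p stood at -0.32 ± 0.14, -0.48 ± 0.14 and -0.15 ± 0.14, and miR-126-5p at -0.27 ± 0.27, -0.44 ± 0.27 and -0.17 ± 0.27. The liver miRNA miR-122-5p stood at 0.12 ± 0.31, -0.09 ± 0.31 and -0.21 ± 0.31, and the pancreas miRNA miR-217 at -2.42 ± 1.14, -1.10 ± 1.14 and 1.33 ± 1.14. miR-34a, a target of p53, stood at 0.81 ± 0.36, -0.27 ± 0.36 and -1.08 ± 0.36, and miR-34c at -0.06 ± 0.25, 0.55 ± 0.25 and 0.61 ± 0.25. None of these 8 passed the threshold over all miRNAs. Adjusted over the list alone miR-126-3p was lower between day 210 and day 30 (0.0167), and between day 210 and day 90 miR-34a was lower (0.0294) and miR-34c higher (0.0319). The same adjustment gave 1 lower erythroid miRNA between day 90 and day 30. Between day 210 and day 30 it gave 2 higher and 2 lower in the neural list and 1 higher and 2 lower in the miR-424 cluster. Between day 210 and day 90 it gave 1 higher and 1 lower in the neural list, 1 higher and 3 lower in the let-7 family and 1 higher epithelial miRNA. The IGF2/H19 list matched 0 entries.

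Across the 3 ages together, 65 of 630 sequences differed (48 pig miRNAs and 17 candidates; limma F test), and 198 had an unadjusted p under 0.05. The count was 20 without day 30 replicate 1, 26 without day 30 replicate 3, 24, 31 and 41 without day 90 replicates 1, 2 and 3, 34 without day 210 replicate 2 and 136 without day 210 replicate 3.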

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

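The common floor, the GC correction, the restriction to pig miRNAs and that to a GC content of at most 60% were chosen after the results were seen; the other alternatives were planned. Both rescalings kept the counts close, at 7, 63 and 52 or 7, 55 and 49 called miRNAs for day 90 against day 30, day 210 against day 30 and day 210 against day 90. The stricter filter gave 35 for day 210 against day 30 and 32 for day 210 against day 90, with 366 sequences tested, and no filter gave 5 lists for day 210 against day 30. Without the mean-variance trend 24 miRNAs were called between day 210 and day 90, and 37 among the 3 ages; the split was 15 higher and 25 lower between day 210 and day 30, and 7 and 17 between day 210 and day 90. Sample weights gave 81 (40 higher, 41 lower), 109 and 100 for the pairwise comparisons and 168 for the 3 ages. A fit of only the ages compared gave 29, 11 and 14, against 7, 58 and 51 in the main fit. The main fit takes 1 spread from all 3 ages. Spearman correlations ran from 0.931 to 0.956 within day 210, from 0.967 to 0.972 within day 90 and from 0.954 to 0.974 within day 30. The counts moved in opposite directions, so they do not rank the comparisons by how much changed. With an estimated correlation 0 lists were called in any comparison, against 6, 1 and 3. The common floor gave 13 between day 90 and day 30 and 38 between day 210 and day 30. The GC correction moved the median log2 fold change between day 210 and day 30 from -0.15 to 0.13 and gave 117 there (83 higher, 34 lower), 98 among the 3 ages and 5 lists, and a GC content of at most 60% gave 31 between day 210 and day 90. The causes of these shifts were not tested.

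Leaving out 1 library gave 1 to 20 called miRNAs between day 90 and day 30, 9 to 90 between day 210 and day 30, 8 to 112 between day 210 and day 90, and 20 to 136 among the 3 ages; where 1 age is left with fewer libraries, its spread is taken from the pooled estimate. The highest count came without day 210 replicate 3 each time; the lowest came without day 90 replicate 1 or 2 (1), day 30 replicate 1 (9), day 90 replicate 1 (8) and day 30 replicate 1 (20). Lists ran from 4 to 6, from 0 (without day 30 replicate 2) to 3 (without day 210 replicate 3; 2 without day 30 replicate 3), and from 1 (without day 90 replicate 1) to 4. The difference in the share of the 10 most abundant miRNAs ran from -1.42 to -0.104 (day 90 against day 30), from 3.23 to 4.51 (day 210 against day 30) and from 3.88 to 5.30 (day 210 against day 90), and with the 5 most abundant the first turned to 0.900. The difference of miR-451 between day 210 and day 30 turned to -0.0134 with TMM rescaling, -0.36 with sample weights, -0.25 without day 30 replicate 2 and -0.56 without day 210 replicate 3, with 0.47 as its highest value (without day 210 replicate 2); the cause was not tested.

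Replicate numbers were checked for pairing: libraries that share a number correlated between -0.10 and 0.19 (9 pairs, median 0.01) after the age means were removed, against -0.15 to 0.11 for other numbers (18 pairs), and 1 of 9 libraries was closest to its own number in both other ages. With the replicate block 1 miRNA was called (higher) between day 90 and day 30, 45 between day 210 and day 30, 47 between day 210 and day 90, and 56 among the 3 ages. Depth limits what the scarce sequences can show, since values under 3.62 to 8.001, depending on the library, are mostly listed at 0.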

Other observations

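All tests in this part except the regroupings of libraries were chosen after the results were seen. miRNAs whose precursors lie within 10000 bases of each other on the pig assembly Sscrofa11.1 moved more alike than chance pairs, as a hypothesis that they share transcripts would have it. Over 45 neighbouring pairs the median absolute difference of log2 fold changes was 0.26 between day 90 and day 30, against a median of 0.48 when precursors were shuffled 100000 times (permutation p 0.0015, adjusted 0.0046). It was 0.46 against 0.68 between day 210 and day 30 (permutation p 0.026, adjusted 0.026) and 0.38 against 0.61 between day 210 and day 90 (permutation p 0.0085, adjusted 0.013); the 3 comparisons share libraries. Between day 210 and day 30 the pairs miR-195 and miR-497 (1.47 ± 0.23 and 1.17 ± 0.16), miR-99a-5p and let-7c (0.58 ± 0.13 and 0.51 ± 0.11) and miR-29b and miR-29a (1.21 ± 0.41 and 1.05 ± 0.11) lay close. Other pairs lay apart, such as miR-450c-5p and miR-542-3p (-0.38 ± 0.23 and -3.64 ± 1.22, the latter at 0 in 2 day 210 libraries). The gap of miR-224 and miR-452 cannot be measured, since miR-224 was at 0 in all day 210 libraries and miR-452 at 0 in all day 30 libraries and at the reporting floor at day 210. The pair miR-451 and mir-144-p5 (0.03 ± 0.49 and -1.54 ± 0.36) also lay apart. Neighbours can also be alike because they are members of 1 family with similar sequences, which this test does not separate.

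The excess of GC-rich sequences among the 29 called higher at day 210 than at day 30 may rest in part on a single library, day 210 replicate 3. Of these risers 8, or 27.6%, had a GC content of at least 70%, against 8.89% of the 630 tested (Fisher's exact test p 0.00231). That test takes the 8 as independent, so its p overstates the excess. mir-4332-p5 and mir-4332-p3 share a precursor, and PC-5p-2838_1485 ends with the bases that begin PC-5p-24063_140. These 2 candidates and PC-3p-42837_55 reached the filter value only in day 210 libraries, so they could be called only as higher. Without day 210 replicate 3, and with the same 630 tested, 6 of the 8 stayed called. Then 13.6% of the 44 risers were GC-rich (Fisher's exact test p 0.267), too few to decide. Of 3 earlier forms of this test, 1 (all 8 above every day 30 library in both other day 210 libraries) decides nothing, because the 8 were chosen as higher at day 210, and 2 applied the filter again, which removed 3 of the 8 untested and left 3 of the other 5 called (7.69% of 39 risers, Fisher's exact test p 1). A GC bias that raised every GC-rich sequence is argued against by 44 annotated mature miRNAs with a GC content of at least 60%. Their median log2 fold change was -0.39 (bootstrap SE 0.13, over these miRNAs and not over libraries), against -0.06 for the 266 with less. Without day 210 replicate 3 it was -0.20 (bootstrap SE 0.14). Against the day 30 means the medians were -0.09, -0.13 and -0.68 in replicates 1, 2 and 3, and -0.10, -0.10 and 0.0009 for those under 60%. Annotated mature miRNAs with a GC content of at least 70%, also 8 but none of them a riser, had a median log2 fold change of -0.67. Over all 56 tested at that level, the 8 risers included, the medians against the day 30 means were 0.26, 0.60 and -0.25 in replicates 1, 2 and 3. A GC bias that lowered GC-rich sequences, as in replicate 3, is not argued against. A GC effect on part of the sequences stays open. After the GC correction the excess ended (9.64% of risers, Fisher's exact test p 0.836). That decides nothing, because the risers went from 29 to 83 while 7 of the 8 stayed called. Their median log2 fold change went from 5.47 to 4.40 (median SE from 1.19 to 1.005). Fragments of other GC-rich RNA also stay open, since 5 of the 8 had a length outside 21 to 23 nt, against 24 of the 48 other GC-rich sequences (Fisher's exact test p 0.707), and a difference of age also stays open and was not tested.

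The 16 sequences called lower at day 210 than at day 30 with a mean under 50 could in part reflect the lower depth of the day 210 libraries, since 9 of them were listed at 0 in all 3. When all libraries were given 1 common floor, 7 of the 16 stayed past the threshold and 0 of these 9 did; for the 7 the median log2 fold change went from -3.76 (median SE 0.711) to -1.76 (0.313). A common floor shrinks each change that starts near it, so the calls that ended do not show that these falls came from depth. For them this test cannot tell depth and age apart. The value that stands for 5 reads was 5.33, 6.46 and 8.001 in day 210 replicates 1, 2 and 3. All day 30 values of miR-33b-3p and miR-10390_L-5 lay above these levels, while mir-218b-p3 and mir-20b-2-p3 each had a day 30 value below them. Of the 13 other falls 9 stayed called.

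The lower erythroid miRNAs at day 210 (miR-486 -1.23 ± 0.21, mir-144-p5 -1.54 ± 0.36 against day 30) may reflect a smaller share of red cell RNA, which would lower miR-451 alike. The change of miR-451 exceeded that of miR-486 by 1.26 ± 0.64 on the log2 scale (n = 3), just under 2 standard errors; its exact permutation p of 0.2 decides nothing, since 3 against 3 allow none under 0.1. Day 210 replicate 3 held the highest miR-451 value of that age, 20851, and without that library the change of miR-451 was -0.56. The explanation therefore stays open, as does a change within the red cells of older spleens, which was not tested.

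Regrouping the libraries gave a reference for the counts. For the 3 ages together 1 of 100 groupings drawn, the real one, gave as many as 65 called miRNAs, and the highest other gave 31. Few random groupings of these libraries would therefore give as many. That speaks only to these libraries, since the labels do not say that they came from separate animals. For the pairwise comparisons 10 splits are too few for a share under 0.05. The real count and the highest other were 7 and 0 for day 90 against day 30, 58 and 0 for day 210 against day 30, and 51 and 0 for day 210 against day 90; 1 split of 10 reached the real count each time. For lists they were 6 and 3 (1 split), 1 and 3 (7 splits) and 3 and 4 (4 splits). In both comparisons with day 210, other splits thus gave at least as many list calls as the real ages.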
